A study of Arabis alpina with 18 samples.

How the data were processed

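Poly(A) RNA from 1 µg of total RNA was made into directional libraries and sequenced as single reads of 100 bases on a HiSeq2500, per the labels' protocols. The deposited count table holds raw read counts per gene for the 18 libraries, and the submitters' processing notes name STAR, HTSeq 0.5.4p1, DESeq and DESeq2. The deposited lists of changed genes hold normalised group means (a signal scaled by size factors), log2 fold changes, fold ratios, p-values and adjusted p-values made by the authors, per the file headers. Their group means lay within 1% plus 0.01 normalised counts of means computed here from the counts with median-of-ratios factors for 214, 569 and 1169 listed genes. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, and no coordinates were used. Counts of antisense or overlapping genes and of near-identical copies are therefore uncertain.

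The table has 34220 genes and 5 summary entries that name no gene. Those entries were kept out of library sizes and tests: reads outside genes came to 7.76 to 16.6% per library and ambiguous reads to 2.01 to 3.60%. Reads outside genes took 13.7 to 16.6% in pep1-1 and 14.0 to 14.7% in eop055 apices at 5 weeks. Groups and replicate numbers were taken from the labels. Replicate pairs had a chi-square per gene of 1.50 to 24.7, so no library was an identical copy of another. The lowest value was for pep1-1 leaf replicates 2 and 3, against 4.08 and 4.14 for replicate 1 with each. Technical replicates are not excluded for that pair.

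Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 6 groups, leaving 21275, and libraries were scaled by TMM (factors 1.15 to 1.27 in apices and 0.651 to 0.730 in leaves). The 10 most abundant genes took 2.47 to 3.47% of counts in apices and 10.8 to 11.8% in leaves. All 18 libraries entered 1 fit of 6 group means with robust dispersions, and each comparison was tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 9.65%. Libraries held 7987096 to 14132723 gene counts, so genes near 1 CPM rest on few reads, and their folds are given with counting limits: a group at 0 counts was set to a floor of 3 counts over the group, and groups of 1 to 3 counts were given a ratio with an exact Clopper-Pearson 95% interval.

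The comparisons were eop055 against pep1-1 in each of the 3 tissues and ages, 5 against 3 weeks in apices of each genotype, the difference of the genotype effect between ages and between tissues, and leaf against apex in pep1-1. The test was tried on simulated counts with 200 changed genes per comparison. It recovered 88.1% of 67 genes changed 2-fold among 21141 genes tested for 3-week apices, 88.1% of 67 among 21113 for 5-week apices and 84.8% of 66 among 21106 for leaves, with false calls of 6.25%, 2.34% and 4.65%. Changes were placed only in genes of at least 1 CPM in pep1-1. All groups were drawn with the same spread per gene, so the wider spread of the eop055 leaf libraries was not simulated.

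Gene names were taken from the authors' deposited lists, which gave an Arabidopsis locus for 1401 of 1816 distinct genes. Of these 1399 matched 1 count row and were named. The 17 gene lists, the rule for named genes, the tests of the comparisons and the alternatives were fixed before the data were examined. Several tests of explanations in the closing section were written later and are named there. The rule named, for each genotype comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between genotypes. It added every called member of the flowering, floral organ and floral repressor lists and up to 4 called members of each other list, and the 5 largest rises and falls in the other comparisons. Lists were counted and not tested for enrichment, because only genes the authors had called carry names. The shoot meristem, cell division and photosynthesis lists had 0 named members. Alternatives were RLE and upper quartile scaling, no filter, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, an adjusted p of 0.01 and leaving out each library. The 2-fold minimum and the stricter adjusted p were applied to counts of genes and not to single named calls. Figures were drawn with matplotlib 3.10.9.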

Results

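Messenger RNA was measured by RNA sequencing in Arabis alpina, a perennial relative of Arabidopsis, in plants of the accession Pajares grown in long days. The 18 libraries fell into 6 groups of 3: dissected shoot apices at 3 weeks, dissected shoot apices at 5 weeks and leaves 5 and 6 of plants at 5 weeks, each from the pep1-1 mutant and from the mutant called eop055. PEP1 is the A. alpina ortholog of the Arabidopsis floral repressor FLC, and the series concerns the control of flowering by the TOE2 ortholog, an AP2-like floral repressor. The lesion of eop055 is not given in the sources used here. Gene counts summed to between 7987096 and 14132723 per library. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these libraries, part of which can be technical.

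No gene named here was paired with the Arabidopsis loci of TOE2 or FLC (0 and 0 genes), so the levels of TOE2 and PEP1 were not analysed here and the genotype labels were not checked against a targeted gene. Names come from the authors' deposited lists of changed genes, which paired 1399 genes with 1 count row and an Arabidopsis locus, 1381 of them tested. Membership of the gene lists below was therefore limited to genes that the authors had called in these same libraries. A member is called measured below where it carries such a name and was tested. Other members may be among the genes counted but could not be matched to them. The counts of members are not independent evidence of a direction, whether adjusted over all 21275 genes tested or over the list alone. Along the first principal component, 86.7% of the variance, the 6 leaf libraries lay between 179 and 221 and the 12 apex libraries between -118 and -73.2. The second component, 4.24% of the variance, held the 3-week apices between 35.0 and 45.3 and the 5-week apices between -48.7 and -29.0.

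The first question was how eop055 apices differed from pep1-1 apices at 5 weeks. Of the list of genes that promote flowering or mark floral meristems, 6 of the 6 members named here rose in eop055 (6 adjusted over the list alone). Other members of that list, such as FT and SOC1, carry no name here and were not assessed. SPL5 (Aa_G1050h1), a target of the age pathway, stood at 35.6 ± 10.6 CPM in eop055 against 3.70 ± 1.57 CPM in pep1-1 (SD, n = 3 each), 9.69-fold higher. LFY (Aa_G61540h1), the floral meristem identity regulator, stood at 17.1 ± 6.57 against 3.38 ± 0.157 CPM, 5.01-fold higher. SPL4, SPL9 and FD, the bZIP partner of florigen, rose by 2.87 ± 0.295, 1.01 ± 0.113 and 1.34 ± 0.158 on the log2 scale (± SE). AP1 (Aa_G283230h1), the floral meristem and sepal identity gene, had 272 counts over the eop055 libraries and 1 over the pep1-1 libraries, a ratio of 220 with a 95% counting interval of 39.1 to 8710. Without pep1-1 replicate 1 the ratio was 127, and without replicate 2, which held the 1 count, AP1 was at least 53.4-fold higher.

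Floral organ identity genes rose with them, 6 of 6 measured members (6 adjusted over the list alone). The petal and stamen gene PI (Aa_G68100h1) had 216 counts against 1, a ratio of 174 with a 95% counting interval of 31.0 to 6920. Its partner AP3 rose by 4.32 ± 0.740 on the log2 scale, and SEP4 had 236 counts against 2, a ratio of 95.3 with an interval of 26.1 to 791. SEP1 had 89 counts against 0 and was at least 24.0-fold higher, against a floor of 3 counts over the group. Without eop055 replicate 3 AP3 was 11.3-fold instead of 19.9-fold higher and SEP1 at least 12-fold higher. Without pep1-1 replicate 1 the values were at least 33.6-fold for PI, at least 13.8-fold for SEP1 and a ratio of 55.1 for SEP4, which was at least 44-fold higher without pep1-1 replicate 3. SPL8 (Aa_G106150h1) stood at 63.5 ± 1.75 against 11.1 ± 1.91 CPM, and CRC, which acts in carpels, rose by 1.62 ± 0.247 on the log2 scale. SEP3 was too low to be tested and had 8, 5 and 27 counts in the eop055 libraries against 0 in each pep1-1 library. Intervals and floors cover counting error only. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.54e-08 for SPL5, 4.35e-06 for LFY, 1.39e-06 for AP1, 0.000284 for AP3 and 3e-12 for SPL8. Floral genes were most abundant in eop055 replicate 3: AP1 stood at 5.56, 3.00 and 9.33 CPM and LFY at 13.7, 12.8 and 24.6 CPM in replicates 1, 2 and 3.

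**Figure D1:**
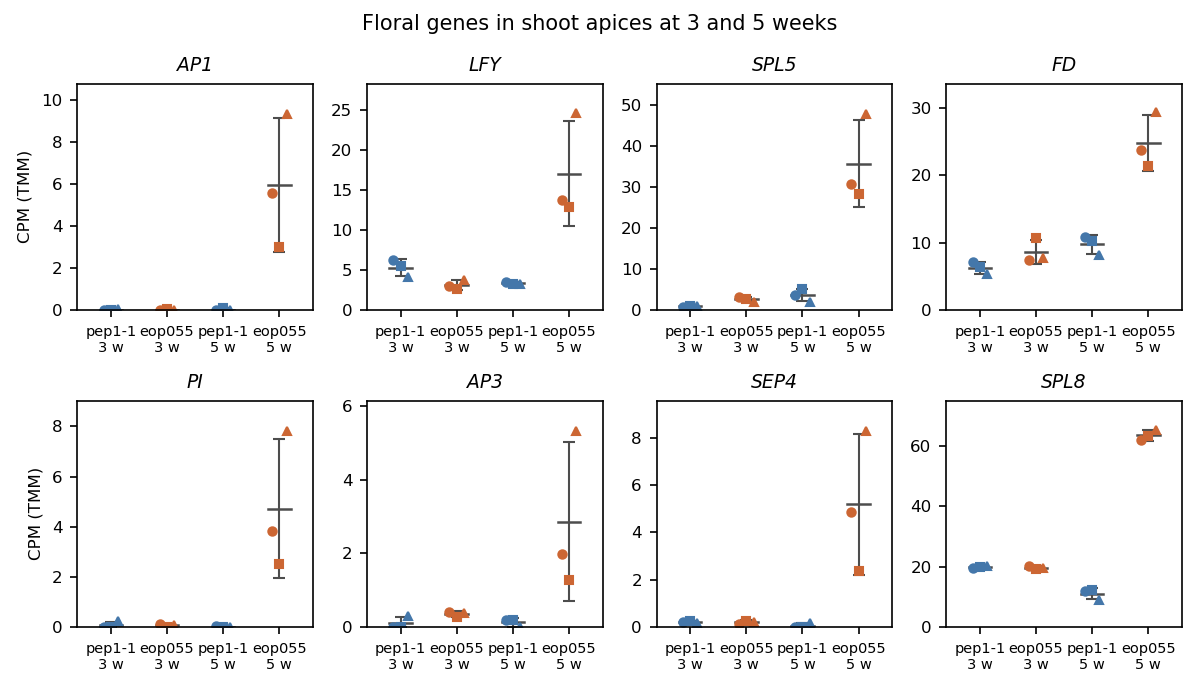
Normalised expression in CPM (TMM scaling) of 8 floral genes in apices of pep1-1 (blue) and eop055 (orange) at 3 and 5 weeks (w); circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are means and bars are SD (n = 3), with the lower bar ending at 0. LFY stood at 17.1 CPM in eop055 at 5 weeks against 3.38 CPM in pep1-1, and the eop055 libraries at 5 weeks lay above every other apex library for each of the 8 genes.

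Other genes with large rises at 5 weeks included REM22, with 254 counts against 0 and at least 68.4-fold higher (39.5 without pep1-1 replicate 1, 43.8 without eop055 replicate 3), and the MADS-box gene AGL6, which rose by 4.69 ± 0.336 on the log2 scale. LOX2 (Aa_G49590h1), a chloroplast lipoxygenase of jasmonate synthesis, stood at 45.7 ± 12.8 against 2.92 ± 1.08 CPM, 16.2-fold higher. AT3G53140, ASPGB1, PILS3 and LOG5, a cytokinin-activating enzyme, rose by 3.78, 3.52, 2.96 and 2.89 on the log2 scale. The flavonol synthase gene FLS1 was 2.82-fold higher, the only measured member of the flavonoid list, and the auxin-conjugating GH3.3 rose by 1.05 ± 0.151, 1 of 2 in the auxin list (1 and 1 adjusted over the list alone). In the jasmonate and ethylene list LOX2 rose, JAZ9 and MYC2 fell by 1.03 ± 0.244 and 1.14 ± 0.352 and 6 did not pass the test (1 higher and 2 lower adjusted over the list alone). In the clock list CCA1 and LHY rose by 0.97 ± 0.206 and 0.42 ± 0.134, PRR5 fell by 0.60 ± 0.149 and 4 did not pass the test (4 higher and 1 lower adjusted over the list alone). RAB18 rose and RD29A fell in the cold and abscisic acid list of 6, by 1.42 and 0.64, and HSP90.1, the only measured heat shock gene, rose by 1.13 ± 0.321.

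Among the falls, the regulators of aliphatic glucosinolates MYB28 and MYB29 changed most within their list. MYB28 (Aa_G606850h1) fell by 2.47 on the log2 scale, 5.52-fold lower, and MYB29 stood at 0.237 ± 0.0959 CPM in eop055 against 2.34 ± 0.406 CPM in pep1-1, 9.39-fold lower. With SOT18, 3 of 10 measured glucosinolate genes fell and 7 did not pass the test (3 lower adjusted over the list alone). AK3, AT1G27030, FLA9, DIN10, TPPF and TLL1 fell by 2.93, 2.55, 2.42, 2.40, 2.38 and 2.33 on the log2 scale. GA3OX1, which makes active gibberellin, and WRKY54 fell by 1.19 ± 0.165 and 1.33 ± 0.175, each the only member of its list called, out of 3 and 10 measured. In the immune list of WRKY54, 3 members were called lower when only the groups compared were fitted and 2 with DESeq2. The cytokinin response gene ARR5, the only measured member of its list, fell by 0.99 ± 0.184. AT5G28885 had 8 counts in eop055, all in replicate 2, against 145, 87 and 122 in the pep1-1 libraries. The floral repressors TEM1 and TEM2 gave log2 fold changes of -0.73 ± 0.266 and -0.37 ± 0.537 and did not pass the test (1 lower adjusted over the list alone).

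In all, 3077 of 21275 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1524 higher and 1553 lower in eop055, and 717 of them also changed at least 2-fold. On simulated counts with changes only in genes of at least 1 CPM in pep1-1, the same test recovered 88.1% of genes changed 2-fold in this comparison. It recovered 64.2% of those changed 1.5-fold, with 2.34% false calls. Under a filter of 50 counts in 3 libraries 2 of the 6 floral organ rises and 5 of the 6 flowering rises were counted, since the other genes were then not tested. Named calls were followed over the alternatives other than the 2-fold minimum and the stricter adjusted p. Some that held, such as CCA1 and RD29A, changed less than 2-fold. Of 44 named calls 37 held in every alternative that tested them, AP1, SEP4, SEP1, PI and AP3 being untested under the filter of 50 counts: MYC2 was lost with the replicate block and with no filter, leaving out pep1-1 replicate 1, 2 or 3 ended 2, 4 and 5 of them and leaving out eop055 replicate 1, 2 or 3 ended 3, 5 and 2, among LHY, PRR5, MYC2, JAZ9, RAB18 and HSP90.1, with adjusted p from 0.0531 to 0.174 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and SOT18 and JAZ9 were not called when only the groups compared were fitted.

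The next question was how the genotypes differed earlier, in apices at 3 weeks. The clock and photoperiod list moved in both directions: 3 of its 7 measured members rose, 3 fell and 1 did not pass the test (3 and 4 adjusted over the list alone). The morning genes CCA1 and LHY and the CONSTANS-like COL1 rose by 1.25 ± 0.243, 1.25 ± 0.144 and 1.44 ± 0.215 on the log2 scale. FKF1, a blue-light receptor of the photoperiod pathway, stood at 1.38 ± 0.957 CPM in eop055 against 5.83 ± 0.727 CPM in pep1-1 (SD, n = 3 each), 4.32-fold lower (a fall of 2.11 on the log2 scale, 2.76 without eop055 replicate 3). LUX and PRR5, named after their values were seen because they complete the count, had log2 fold changes of -1.07 ± 0.206 and -0.67 ± 0.150, and PRR5 was not called without pep1-1 replicate 3 or eop055 replicate 1 or 2. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 5.43e-05 for LHY, 0.00365 for CCA1, 0.000306 for COL1 and 0.00588 for FKF1.

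Glucosinolate genes were called in both directions at 3 weeks. CYP79F1 and CYP83A1, of the aliphatic branch, rose by 1.46 ± 0.236 and 1.52 ± 0.343 on the log2 scale. CYP79B3 and CYP79B2, which lead into the indole branch, were 8.59-fold and 3.47-fold lower. CYP83B1 and SOT16, named after their values were seen, had log2 fold changes of -1.07 ± 0.179 and -1.13 ± 0.289, and SOT16 was not called with any 1 of the 6 libraries left out. In this list 2 of 10 measured members rose, 4 fell and 4 did not pass the test (2 and 4 adjusted over the list alone), among them MYB28, MYB29 and SOT18 of the aliphatic branch, with log2 fold changes of 0.35 ± 0.209, 0.08 ± 0.252 and -0.22 ± 0.195. With only the groups compared, or without pep1-1 replicate 2 or 3, 2 of the 4 falls were called. The rise of CYP83A1 was lost with the replicate number as a block and without pep1-1 replicate 2 or 3 or eop055 replicate 1 or 2, and its adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ranged from 0.0232 to 0.171 over its 13 alternatives.

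**Figure D2:**
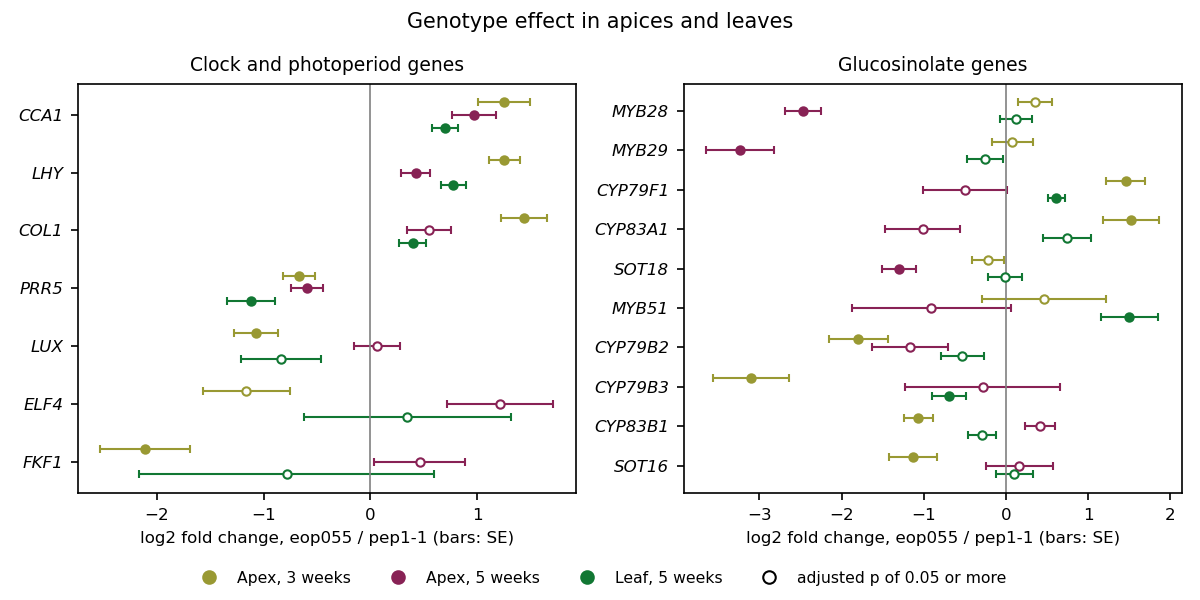
Log2 fold change of eop055 over pep1-1 (bars, SE) for 7 clock and photoperiod genes and 10 glucosinolate genes in apices at 3 weeks, apices at 5 weeks and leaves at 5 weeks; filled points passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MYB28 lay at -2.47 in 5-week apices and at 0.35 in 3-week apices, while CCA1 lay above 0 in all 3 comparisons.

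Flowering and floral organ genes were also counted at 3 weeks. Of 6 measured members of the flowering list only SPL5 passed the test, at 2.71 ± 0.579 CPM in eop055 against 0.907 ± 0.121 CPM in pep1-1, 2.96-fold higher (3 higher and 1 lower adjusted over the list alone). That call was lost with the replicate number as a block and when pep1-1 replicate 1, 2 or 3 or eop055 replicate 1 or 2 was left out, with an adjusted p between 0.000731 and 0.0922 over its 13 alternatives in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. None of the 6 measured floral organ genes or 2 floral repressors passed edgeR's test (0 adjusted over the list alone). AP1 had 1 count over each group of 3 libraries, so no fold can be given.

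Among the largest rises at 3 weeks were the chitinase homologs AT2G43590 and AT2G43620, ATBBE7 and ALPHA DOX2, an alpha-dioxygenase, which rose by 2.51 ± 0.432, 2.34 ± 0.441, 2.12 ± 0.427 and 2.00 ± 0.326 on the log2 scale (AT2G43590 by 1.88 without eop055 replicate 2). The amino acid exporter SIAR1 stood at 23.5 ± 4.32 against 7.34 ± 1.25 CPM, and IMD1, of leucine and glucosinolate synthesis, rose by 1.51 ± 0.201. JMJD5, a histone demethylase homolog with a clock role, stood at 1.47 ± 0.321 CPM in eop055 against 10.8 ± 1.85 CPM in pep1-1, 7.39-fold lower. AT1G07050, AT2G13840 and the receptor kinase PXC2 fell by 1.94, 1.66 and 1.18 on the log2 scale. AT5G28885 (Aa_G795460h1) had 319 counts in pep1-1 and 0 in eop055, at least 102-fold lower (66.6 and 66.8 without eop055 replicate 1 and 2). The jasmonate repressors JAZ9 and JAZ10 fell by 1.13 ± 0.232 and 0.90 ± 0.219, 2 of 9 measured members of the jasmonate and ethylene list (1 higher and 5 lower adjusted over the list alone). Neither was called without pep1-1 replicate 3 or eop055 replicate 1 or 2, and JAZ10 was not called without pep1-1 replicate 2 or eop055 replicate 3 either, with adjusted p between 0.000585 and 0.141 over its 13 alternatives in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. GH3.3 fell by 0.56 ± 0.143, 1 of 2 in the auxin list (1 lower adjusted over the list alone), and was not called without pep1-1 replicate 1, 2 or 3 or eop055 replicate 2 or 3 (adjusted p between 0.00785 and 0.204 over its 13 alternatives in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). No measured member of the salicylic acid (10), cold and abscisic acid (6), gibberellin (3), senescence (2), heat shock (1), flavonoid (1) or cytokinin (1) lists was called by edgeR's test.

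In all, 783 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 3 weeks, 548 higher and 235 lower, and 190 also changed at least 2-fold. The count rose to 1712 when only the groups compared were fitted, and fell to 359, 378 and 375 without pep1-1 replicate 2, pep1-1 replicate 3 and eop055 replicate 2. For named calls the 2-fold minimum and the stricter adjusted p were again left aside. Of 29 named calls 14 held in every alternative that tested them, ChiC being untested under the filter of 50 counts: the fit of only the groups compared ended 9, among them AT2G43590, AT2G43620, ATBBE7, ALPHA DOX2, CYP79B2 and JAZ9, the replicate block ended 6, among them AT2G43590, AT2G43620, CYP83A1 and SPL5, leaving out pep1-1 replicate 1, 2 or 3 ended 2, 11 and 12, and leaving out eop055 replicate 1, 2 or 3 ended 5, 9 and 2, with adjusted p from 0.0507 to 0.204 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

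Leaves at 5 weeks gave the largest number of genes changed by genotype. The lead was small when only the groups compared were fitted, with 3424 genes in leaves and 3204 in 5-week apices. Of 10 measured members of the salicylic acid and immune list 8 rose in eop055 and 2 did not pass the test (9 higher and 1 lower adjusted over the list alone). The authors' leaf lists, a source of the names, held 1027 genes higher and 150 lower. Named genes thus lean towards rises in leaves whatever their function, in this list and those below. WRKY40 (Aa_G462530h1) stood at 425.8 ± 295 CPM in eop055 against 35.2 ± 10.3 CPM in pep1-1 (SD, n = 3 each), 12.1-fold higher (a rise of 3.59 on the log2 scale, 2.98 without eop055 replicate 2). WRKY46, the oxidase gene RBOHD and the pathogenesis-related gene PR1 rose by 2.13 ± 0.439, 1.52 ± 0.206 and 1.84 ± 0.484 on the log2 scale (PR1 by 0.64 less without eop055 replicate 3). In the jasmonate and ethylene list 6 of 9 members rose and 3 did not pass the test (7 adjusted over the list alone), among them LOX3 at 104.3 ± 35.8 against 32.0 ± 1.02 CPM and JAZ1, which rose by 2.12 ± 0.417. Both measured floral repressors rose: TEM2 stood at 233 ± 119 against 42.8 ± 3.94 CPM and TEM1 was 3.61-fold higher (2 adjusted over the list alone).

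Genes of abscisic acid and cold response moved both ways in leaves, 4 higher and 2 lower of 6 measured (4 and 2 adjusted over the list alone). RAB18, an abscisic acid responsive dehydrin, stood at 62.8 ± 9.30 against 17.9 ± 1.68 CPM, and NCED3 and ABI2 rose by 1.34 ± 0.263 and 1.12 ± 0.107 on the log2 scale. RD29A and GOLS3, named after their values were seen, had log2 fold changes of -1.12 ± 0.126 and -1.06 ± 0.237. The senescence genes NAP and SAG21, both of the 2 measured, rose by 3.63 ± 0.672 and 1.41 ± 0.302, although NAP was not called by DESeq2 (adjusted p with Benjamini-Hochberg adjustment 0.331). Of the 3 gibberellin genes, the synthesis gene GA3OX1 fell by 0.99 ± 0.191 while GA2OX6 and GA2OX2, which inactivate gibberellin, rose by 1.72 ± 0.329 and 1.33 ± 0.467 (2 and 1 adjusted over the list alone). GA2OX2 lost its call in 9 of 13 alternatives, and neither rise was called when only the groups compared were fitted. CCA1 and LHY rose by 0.70 ± 0.122 and 0.78 ± 0.117 and PRR5 fell by 1.12 ± 0.227, in a clock list with 3 higher (COL1 the other), 1 lower and 3 not called. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00108 for WRKY40, 5.73e-05 for LOX3, 0.000125 for TEM2 and 3.21e-09 for RAB18. These values rest on a spread pooled over all 6 groups, while the eop055 leaf libraries were the least alike of any group. Over the alternatives, in edgeR's test or DESeq2 with Benjamini-Hochberg adjustment, the adjusted p reached 0.0454, 0.0182, 0.026 and 6.85e-05 for these genes.

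The largest rises in leaves also included ERF022, UMAMIT36, CYP72A8, AT2G39980, ARGOS, GPAT3, MIOX2 and AT1G69790, at 4.55, 4.27, 4.20, 3.93, 3.82, 3.73, 3.67 and 3.61 on the log2 scale (3.78 for ERF022 and 3.34 for AT2G39980 without eop055 replicate 2). The largest falls included AT5G28885, with 189 counts in pep1-1 against 0 and at least 56.4-fold lower (36.6 and 35.8 without eop055 replicate 1 and 3), and DOT1, the nitrate transporter gene NRT2.3, UGT72B3, the ethylene synthesis gene ACS4 and HB4, which fell by 2.39, 2.38, 2.25, 2.13 and 2.06 (UGT72B3 by 3.19 without eop055 replicate 3). PXC2 stood at 5.39 ± 0.316 CPM in eop055 against 26.4 ± 0.549 CPM in pep1-1. In the auxin list IAA14 rose by 1.86 ± 0.248 and GH3.3 fell by 2.01 ± 0.524, ARR5 and HSP90.1 rose by 1.04 ± 0.170 and 1.00 ± 0.230, and among 10 glucosinolate genes MYB51 and CYP79F1 rose and CYP79B3 fell (2 and 1 adjusted over the list alone). FLS1 had a log2 fold change of 0.15 ± 0.233 and did not pass the test. Of 6 measured flowering genes and 6 floral organ genes none passed edgeR's test in leaves. AP1, LFY and CRC had 0 counts in the leaf libraries of both genotypes.

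**Figure D3:**
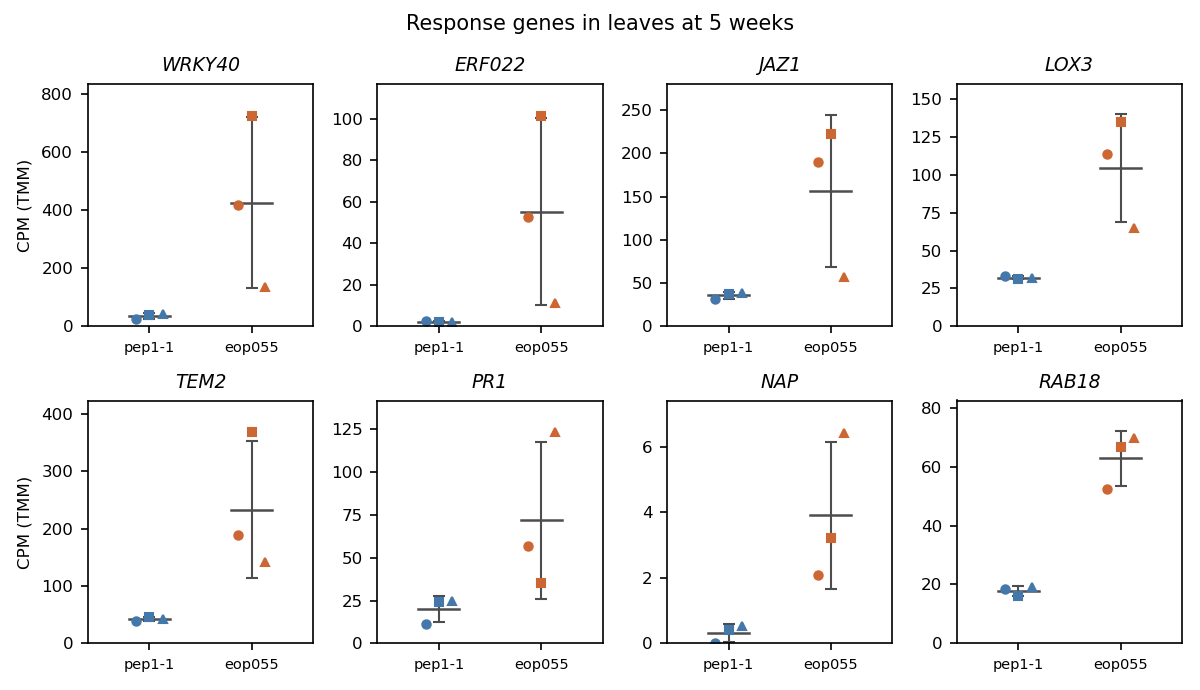
Normalised expression in CPM (TMM scaling) of 8 response genes in leaves of pep1-1 (blue) and eop055 (orange) at 5 weeks; circles, squares and triangles are replicates 1, 2 and 3, lines are means and bars are SD (n = 3). For WRKY40, ERF022, JAZ1, LOX3 and TEM2 eop055 replicate 3 was the lowest eop055 library, at 134.4 CPM for WRKY40 against 419 and 724 CPM, and for PR1, NAP and RAB18 it was the highest.

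The eop055 leaf libraries were the least alike of any group. On the first principal component of the leaf libraries they lay at 42.6, 61.5 and 13.9 against -45.6, -36.1 and -36.3 in pep1-1, and the floral repressor, immune and jasmonate genes named above, other than PR1, were closest to pep1-1 in replicate 3. Without that replicate 5755 genes were called, against 5661 with it, 3187 higher and 2474 lower, of which 1400 changed at least 2-fold (1093 higher, 307 lower). Upper quartile scaling moved the median log2 fold change of all genes from -0.0109 to -0.123 and turned the split to 2418 higher and 4519 lower of 6937. The leaf genes named by the rule fixed beforehand kept their directions there, although COL1 and GA2OX2 were then not called.

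Fitting only the 6 leaf libraries reduced the calls to 3424, and 11 named genes were not called, among them ERF022, WRKY46, PR1, JAZ1 and GA2OX6, with adjusted p from 0.0566 to 0.215 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In that fit 2 members of the jasmonate list were higher instead of 6, and 6 of the immune list instead of 8. The 2-fold minimum and the stricter adjusted p were left aside for named calls here too, and CCA1 and LHY changed less than 2-fold. Of 49 named calls 34 held in every alternative that tested them, UMAMIT36, AT1G69790, CBF3 and NAP being untested under the filter of 50 counts in 3 libraries: the replicate block ended 4 (ERF022, GA2OX2, LOX4 and MYC2), DESeq2 ended 2 (NAP and LOX4), leaving out pep1-1 replicate 1, 2 or 3 ended 6, 6 and 4 and leaving out eop055 replicate 1, 2 or 3 ended 3, 4 and 1, with adjusted p of lost calls from 0.0517 to 0.226 when a library was left out and from 0.0510 to 0.135 with the block in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, among PR1, LOX4, MYC2, CBF3, COL1, GA2OX2, CYP79B3 and GH3.3.

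Changes between 3 and 5 weeks were described in each genotype. Reads outside genes took 10.6 to 11.8% in the 3-week and 13.7 to 16.6% in the 5-week apex libraries. A difference between libraries of the 2 ages therefore cannot be told apart from age. In pep1-1 apices 8285 genes changed (3971 higher, 4314 lower at 5 weeks), with ZPR2, AT3G59270, FAF2 and WRKY12 rising by 2.70, 2.43, 2.08 and 1.79 on the log2 scale. CYP79C2, LOX2, ST2A and GSTF3 fell by 4.62, 3.05, 2.75 and 2.75 there (CYP79C2 by 5.27 without replicate 1 at 5 weeks). In pep1-1 4 of 6 flowering genes, SPL5, SPL4, FD and SPL9, rose (SPL5 by 1.99 ± 0.355), while 2 of 6 floral organ genes fell, SPL8 and CRC, by 0.83 ± 0.126 and 0.89 ± 0.258. There SPL4 was not called without replicate 1 at 5 weeks or 1 or 2 at 3 weeks, nor CRC without replicate 1 at 5 weeks or 2 at 3 weeks. In eop055 apices 7643 genes changed (3521 higher, 4122 lower), and 6 of 6 flowering genes and 6 of 6 floral organ genes rose, CRC not without replicate 3 at 5 weeks. AP1 had 272 counts at 5 weeks against 1 at 3 weeks, a ratio of 248 with a 95% counting interval of 44.1 to 9830 (161 without replicate 1 at 3 weeks, and at least 54-fold without replicate 2), and AGL6 and SPL5 rose by 4.66 and 3.70. ChiC was at least 96.9-fold lower at 5 weeks (62.6 without replicate 2 at 5 weeks). CYP79C2, ATBBE7 and GSTF2, with 23, 5 and 8 counts at 5 weeks, fell by 6.95, 6.24 and 5.86, and by 7.75, 6.94 and 7.19 without replicate 1 at 5 weeks. The measured floral repressors TEM1 and TEM2 fell with age in pep1-1 by 0.68 ± 0.243 and 1.56 ± 0.447 and in eop055 by 1.36 ± 0.252 and 1.90 ± 0.448. In pep1-1 neither was called without replicate 1 or 3 at 5 weeks, nor TEM1 without replicate 1 or 2 at 3 weeks. Adjusted over the list alone, the flowering list held 4 higher and 1 lower in pep1-1 and 6 higher in eop055. Upper quartile scaling turned the splits to 4419 higher and 3896 lower in pep1-1 and to 3962 and 3758 in eop055.

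The difference of the genotype effect between ages was itself tested. It passed for 2265 genes, 955 with a log2 fold change of eop055 over pep1-1 that was more positive at 5 than at 3 weeks and 1310 with a more negative one. Of the flowering and floral organ lists 4 of 6 members each passed with a more positive effect at 5 weeks: SPL5, SPL9, FD and LFY, and SEP4, PI, SPL8 and CRC, including LFY by 3.07 ± 0.366, SPL8 by 2.52 ± 0.170 and SPL5 by 1.71 ± 0.473 on the log2 scale (6 and 5 adjusted over the list alone). With 1 library left out the call of SPL5 was lost for 3-week replicates 2 and 3 of either genotype. That of FD was lost for 5-week replicate 3 of either genotype, pep1-1 3-week replicate 1 and eop055 3-week replicate 3. PI, with 4, 3 and 1 counts in 3 of its 4 groups, was not called without pep1-1 5-week replicate 2 or 3, pep1-1 3-week replicate 3 or eop055 3-week replicate 2. In the glucosinolate list 5 members had a more negative effect at 5 weeks (MYB28 at -2.82 ± 0.303, MYB29 at -3.31 ± 0.496, CYP79F1, CYP83A1 and SOT18), and CYP83B1 had a more positive one (3 and 5 adjusted over the list alone). Those of CYP79F1 and SOT18 were each lost with some libraries left out, 7 and 6 of the 12. Between leaf and apex at 5 weeks the genotype effect differed for 4273 genes, 2325 more positive in leaf and 1948 more negative. Upper quartile scaling turned that split to 1784 and 3317 of 5101, and moved the median of all genes from -0.021 to -0.132. TEM1 and TEM2 had more positive effects in leaf by 2.58 ± 0.348 and 2.81 ± 0.628, as did 5 of 10 immune genes and 6 of 9 jasmonate genes (5 and 8 adjusted over the list alone, and WRKY40, WRKY53, JAZ6 and JAZ9 lost with 1 library left out), while LOX2 differed by -4.09 ± 0.470.

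Called genes overlapped between the 3 genotype comparisons, which share no library but come from 1 fit with 1 estimate of spread per gene. Genes with a small estimated spread are more easily called in each of them, in either direction. The numbers given for independent lists are therefore not a chance level. Between 3-week apices and leaves 208 genes were higher in both, against 82.1 for independent lists, and 62 were lower in both, against 27.3. There 31 were higher in 3-week apices and lower in leaves, against 63.7, and 27 the reverse, against 35.2. Between apices at 3 and 5 weeks 92 genes were higher in both, against 39.3, and 50 lower in both, against 17.2, while 123 were higher at 3 weeks and lower at 5 weeks, against 40. The reverse, lower at 3 weeks and higher at 5 weeks, held for 33, against 16.8. With a 2-fold minimum 24 were higher in both, against 2.70, and 13 lower in both, against 0.640. With that minimum 5 were higher at 3 weeks and lower at 5 weeks, against 2.33, and 0 the reverse, against 0.742, so the opposed changes were mostly small. Between 5-week apices and leaves 288 genes were higher in both, against 228, and 247 lower in both, against 181. There 184 were higher in 5-week apices and lower in leaves, against 177, and 232 the reverse, against 233. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.214, 0.0869 and 0.014 for these 3 pairs (Spearman's rho 0.179, -0.0574 and 0.00156). In all 3 comparisons 38 genes were higher and 17 lower, against 5.88 and 1.99 for independent lists. The tissue contrast in pep1-1 served as a check of the tissue labels: 17079 genes differed between leaf and apex at 5 weeks, and the catalase gene CAT2 had 27459 counts in leaf against 1 in apex, a ratio of 35100 with a 95% counting interval of 6300 to 1390000 (at least 6770-fold without apex replicate 1). AT2G44240 and SAQR were at least 530-fold and 491-fold higher in leaf and AT4G30250 at least 563-fold higher in apex (306 and 284 without apex replicate 1, and 374 and 373 without leaf replicate 1 and 2). The median log2 fold change of all genes there was -0.122, and -0.266 under upper quartile scaling and -0.0394 with RLE factors.

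The authors' deposited table held 168 genes higher and 52 lower in eop055 in 3-week apices, 298 and 274 in 5-week apices and 1027 and 150 in leaves. Of the genes of the authors' deposited table with 1 count row, edgeR's test called 108 of 164 and 33 of 50 in the same direction at 3 weeks. At 5 weeks it called 290 of 297 and 246 of 272 of the authors' deposited table in apices, and 988 of 1023 and 143 of 146 in leaves. DESeq2 called 138 of the 164 and 38 of the 50 genes at 3 weeks.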

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

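The tests of a mislabelled sample, of scaling, of a single divergent leaf library and of harvest time were chosen only after the result was seen. The test of leaf tissue and the counts over other splits were fixed beforehand.

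A tested difference of the genotype effect singled out 2265 genes between ages in apices and 4273 genes between leaf and apex at 5 weeks. Among 40 regroupings of the genotypes within each age or tissue, 1 gave as many genes, the real one, and the highest other gave 1111 genes between ages and 2108 between tissues. Such regroupings also break up a genotype effect shared by both ages or tissues. They therefore cannot tell a difference of effects from a genotype effect of any kind. The count of splits reaching the real one was also 1 of 10 for each comparison of 3 against 3 libraries. The highest other count there was 1 gene for 3-week apices against 783, 0 against 3077 for 5-week apices and 21 against 5661 for leaves. It was 0 against 8285 and 1 against 7643 for age in pep1-1 and eop055, and 0 against 17079 for tissue. With 10 splits a share under 0.05 is out of reach.

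Between ages, the genotype effect on the log2 scale was more positive at 5 weeks for SEP4 by 6.43 ± 1.22, JMJD5 by 4.38 ± 0.681, LOX2 by 3.33 ± 0.498, AT5G02230 by 3.16 ± 0.367 and LFY by 3.07 ± 0.366. It differed by -3.57 ± 0.968 for ALPHA DOX2, -3.35 ± 0.895 for AT2G43590, -2.99 ± 0.507 for IPMI2, -2.82 ± 0.303 for MYB28 and -2.73 ± 0.365 for DAAR1. SEP4 and ALPHA DOX2 had 2 and 8 counts in their lowest group, so the fitted difference of SEP4 depends on the prior count and is no bound: it was 5.73 and 9.11 without pep1-1 5-week replicate 1 and 3. That of JMJD5 was 5.18 without pep1-1 5-week replicate 3, and that of AT2G43590 was -2.73 without eop055 3-week replicate 2. The call of AT2G43590 was lost in 9 of 19 alternatives and that of ALPHA DOX2 in 5 of 19, with adjusted p up to 0.108 and 0.138 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

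Between tissues, the effect was more positive in leaf for ERF2 by 6.18 ± 1.07, UMAMIT36 by 5.93, AT5G51470 by 5.92 ± 1.79, CYP72A8 by 5.59 ± 1.18 and SRO5 by 5.52 ± 1.56. It differed by -5.26 ± 0.968 for SEP4, -4.39 ± 0.875 for AT3G07570, -4.09 ± 0.470 for LOX2, -3.44 ± 0.408 for DRB3 and -3.36 ± 0.424 for AT5G53390. SEP4, UMAMIT36, AT5G51470, CYP72A8, SRO5 and AT3G07570 had 2, 2, 0, 3, 1 and 2 counts in their lowest group, so their fitted differences depend on the prior count and are no bound. Without pep1-1 apex replicate 1 they were 4.36 for UMAMIT36, 3.81 for CYP72A8, -4.56 for SEP4 and -7.02 for AT3G07570. Without replicate 3 they were 3.31 for SRO5 and -7.93 for SEP4, and without eop055 apex replicate 3 7.17 for SRO5. Without pep1-1 apex replicate 1 the calls of UMAMIT36 and CYP72A8 were lost (adjusted p 0.209 and 0.285), without pep1-1 apex replicate 3 that of SRO5 (0.450) and without eop055 leaf replicate 1 or 2 that of AT5G51470 (0.0606 and 0.0718), which was also lost with the replicate block (0.0581), all in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

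Floral genes and LOX2 in 5-week eop055 apices could reflect a swapped library or leaf tissue left on the apex. Scores were taken on 39 genes changed alike by genotype in the other 2 settings. They were -0.871 to -0.730 in eop055 and -1.61 to -1.48 in pep1-1, a gap of 0.611. The scores argue against a swap of whole libraries between genotypes among these 6, by a rule set after the result was seen. Mixing of part of a library was not tested. LOX2 would need 2.48% of leaf RNA, but over 30 leaf genes near 0 in pep1-1 apices the median of observed over needed level was -0.000538 and the highest 0.0599. CAT2 would then stand at 54.7 CPM and stood at 0.175 CPM, so mature leaf tissue is excluded as the source. Whether the sampled apices held young flowers was not tested.

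Of leaf genes changed at least 2-fold, 1093 of 1400 were higher in eop055, which scaling or 1 divergent library could produce. The share was 78.1% with TMM, 79.8% with RLE and 66.5% with upper quartile scaling, above the 60% set for scaling to be the cause. With eop055 replicate 1, 2 or 3 left out, 1029, 880 and 1331 genes were higher, each above 0.5 of 1093. With any 1 of the 6 leaf libraries left out 77.3 to 81.6% were higher, above the 60% set, and 230 to 378 genes were lower. The excess of higher genes among the 2-fold calls thus held under these scalings and with any 1 leaf library left out. Its size moved with scaling, and the split among all called genes does depend on scaling. The cut-offs were set after the result was seen, so a contribution of scaling to the excess is not excluded.

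Clock genes in 3-week eop055 apices were weighed against a different hour of harvest between genotypes. All 7 of 7 named clock genes followed a morning and evening split, with CCA1, LHY and COL1 up and ELF4, FKF1, LUX and PRR5 down in sign, against 4 in 5-week apices and 6 in leaves. The split was drawn up after the values were seen and the hour of harvest is not given in the sources used here. In pep1-1 apices from 3 to 5 weeks CCA1, LHY and COL1 rose by 0.89, 1.00 and 0.70 on the log2 scale. There ELF4, FKF1 and LUX had log2 fold changes of -2.09, -1.53 and -0.97, and PRR5 did not pass the test. In eop055 apices CCA1 alone of the 7 passed the test with age, rising by 0.60. The split thus also set 3-week pep1-1 apices apart from 5-week pep1-1 apices. A genotype effect on the clock and a difference in harvest time cannot be told apart.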

How the results depend on the processing

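The alternatives, leaving out each library included, were chosen before the data were examined. Named genes were followed over those other than the 2-fold minimum and the stricter adjusted p. There 2191 results kept direction and call, 145 kept direction without passing the test and 0 reversed. Calls with only the groups compared numbered 1712 in 3-week apices, 3204 in 5-week apices and 3424 in leaves. With a 2-fold minimum they numbered 190 (3-week apices), 717 (5-week apices), 1400 (leaves), 1587 and 1781 (age in pep1-1 and eop055), 757 and 1477 (differences between ages and tissues) and 10448 (tissue). At an adjusted p of 0.01 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment they numbered 323, 1724, 3573, 1114 and 2167 in 3-week apices, 5-week apices, leaves and the differences between ages and tissues. Leaving out 1 library gave 359 to 592, 2197 to 2832 and 4296 to 5755 for the 3 genotype comparisons, 6737 to 7953 and 6211 to 6743 for age, 1515 to 2230 and 3445 to 4888 for the differences and 16589 to 16759 for tissue. Genes shared in direction fell with a 2-fold minimum from 142 to 37, 270 to 39 and 535 to 67. With replicate number as a block the counts were 676, 2783, 5184, 8322, 7697, 1958, 3781 and 17078, and same-numbered deviations correlated at r = -0.177 to 0.0385. The cause of these shifts was not tested. The list test with camera and its alternatives were not run. Floral genes near 0 counts in pep1-1 are limited by depth.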

Other observations

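Of the tests below, the simulation with the spread of 18 libraries in genes of at least 1 CPM over all 18 libraries was fixed beforehand. Those with the spread of 9 libraries, with no shared library and in genes chosen by their level in apices were chosen only after the result was seen.

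Some genes differed between genotypes in all 3 comparisons. AT5G28885 had 95, 115 and 109 counts in pep1-1 3-week apices, 145, 87 and 122 in 5-week apices and 67, 53 and 69 in leaves. In eop055 it had 0 counts in 8 of 9 libraries and 8 in 5-week apex replicate 2. Aa_G514020h1, which carries no name here, had 0 counts in all pep1-1 libraries and 475, 21 and 284 in eop055 3-week apices, 5-week apices and leaves, at least 165-fold, 5.65-fold and 106-fold higher (103 without pep1-1 replicate 3, 3.27 without replicate 1, and 70.3 and 70.2 without replicate 1 and 2). AT4G14096 fell by 3.35, 3.71 and 3.64 on the log2 scale (in leaves by 7.29 without eop055 replicate 3), and WRKY30 rose by 2.15, 2.78 and 1.42. These genes were singled out after their values were seen.

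A hypothesis was that eop055 apices at 3 weeks resemble older pep1-1 apices, so that the genotype effect at 3 weeks might vary with the age effect in pep1-1. Both differences use the 3-week pep1-1 libraries, which alone creates covariance. By its rule the test fixed beforehand, with the spread of 18 libraries, went against the hypothesis. Observed covariance was 0.0159, against 0.0319 in simulations of unchanged groups, or -9.13 SD. With the spread of 9 libraries, chosen later, the simulations gave 0.0300, or -6.78 SD. Each gene was drawn independently of the others, so the SD of the simulations leaves out correlation between genes. Values in SD, here and below, therefore do not measure the strength of evidence for or against the hypothesis. With no library shared the observed covariance was below 0 in those genes, at -0.0172. The part due to the shared libraries was 0.0356 observed, against 0.0362 and 0.0343 simulated. The mean variance between the 3-week pep1-1 libraries was 0.0301 observed, against 0.0415 and 0.0362 simulated. By that second measure the simulations were noisier than the data, which can lower the values in SD. The covariance with no library shared lay below the simulated means of 0.000396 and 0.000262 (SD 0.0022 and 0.00216).

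Those genes include some that reach 1 CPM only through the other 9 libraries, 6 of them from leaves. In genes of at least 1 CPM over the 9 apex libraries compared the simulation test gave -1.59 and 2.33 SD, and in those of at least 10 CPM 31.9 and 84.8 SD, with the spread of 18 and of 9 libraries. The simulated shared part was too high there, at 0.0190 and 0.0170 against 0.0133 observed, and at 0.00788 and 0.00576 against 0.00409, which lowers these values. With no library shared, the mean over 6 pairings in the same 2 gene sets was 0.00275 and 0.0144 at the lowest prior count, with 3 and 6 of 6 pairings above 0, while at prior counts of 0.5 and 2 it was 0.00603 and 0.00951 at 1 CPM, with 5 and 6 of 6 above 0, and 0.0143 and 0.0143 at 10 CPM. The sign depends on the genes included, and the sets that favour the hypothesis were picked after the planned result, so it may hold but stays undecided.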
